A study of Caenorhabditis elegans with 20 samples.

How the data were processed

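Gene expression was measured in whole Caenorhabditis elegans of strain HH142, which carries fer-1(b232ts), a temperature-sensitive allele of a gene needed for functional sperm. Per the labels' protocols, worms hatched in synchrony were kept at 25 °C on the food bacterium Escherichia coli OP50 for 72 h (72hOP, 3 samples), and some were then moved for 4 h to Pseudomonas aeruginosa PA14, a human isolate that infects the worm intestine (76hPA, 3 samples). Infected worms were rinsed in M9 buffer with 200 µg/ml neomycin and put back on OP50 with 50 µg/ml streptomycin for 6 h (82hR), 12 h (88hR) or 24 h (100hR), with 3 samples each. Uninfected controls of the same age stayed on OP50 until 82 h (82hOP, 2 samples) or also received the 6 h of antibiotics (82hOPC, 3 samples). For 82hOPC the design text and the growth protocol differ on the hours on OP50 before the antibiotics, 72 h in the former and 76 h in the latter; the sample name and the labelled age both give 82 h. The labels call the samples biological replicates and do not say what samples with the same number share.

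Per the labels' protocols, total RNA was extracted with Trizol and the RNeasy Plus Universal kit and amplified into Cy3-labelled cRNA with Agilent's Low Input Quick Amp kit. Each sample was hybridised to 1 array of a 1-colour Agilent expression design. Per the file headers, the spot intensity values came from Feature Extraction 11.0.1.1, which subtracted background and detrended within each array, with no normalization between arrays, and probe coordinates were given on ce6 (WS190). The authors' deposited series table holds log2 values of the same arrays. Set against the scanner values of the same array, its columns correlated with log2 processed signal across all 43603 probes at r of at least 0.99894, were not centred per probe and had been quantile normalized in separate sets of 15 and 5 arrays, with column medians of 7.3072 and 6.9949. The submitters' processing notes name Partek; its version and the order of its steps are not given in the sources used here. The table served as an alternative, within a set only.

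The 5 slides held 4 arrays each, and slide and scan coincided. Slide 1 held 72hOP 1, 76hPA 1, 82hOP 1 and 82hOPC 1. Slide 2 held 72hOP 2, 82hR 1, 88hR 1 and 100hR 1. Slide 3 held 76hPA 2, 82hOP 2, 82hOPC 2 and 82hR 2. Slide 4 held 72hOP 3, 76hPA 3, 88hR 2 and 100hR 2. Slide 5 held 82hR 3, 88hR 3, 100hR 3 and 82hOPC 3. Every comparison was therefore also fitted with slide as a block and computed within each slide that held both groups. The share of a comparison's genes that kept their direction within a slide is a description only, since those genes were selected on the same arrays.

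Control spots and spots marked as outliers were left out (73 to 249 outlier spots per array), and repeated spots of 1 probe were averaged. The main value was log2 of the processed signal minus each array's 75th percentile of it, which ran from 1255 to 3495. Between 67.1% and 75.7% of spots per array were well above background, and none were saturated. A probe was kept where it was well above background on all arrays of at least 1 group, which left 31626 probes. Probe names were matched to a RefSeq gene table by systematic name (34542 probes), gene name (1880) or accession (274); 6907 probes stayed unmatched and were left out of every gene count. Of the kept probes 28243 had a gene, and each of the 15858 genes was represented by its kept probe with the highest mean signal. A total of 1629 probes listed several genes. Among the gene and comparison pairs drawn by the rule for naming genes (below), 79 had several probes, and in 4 of them the probes differed in sign (lev-11 and col-7 after infection, spp-23 in the age comparison, mrps-25 at 24 h against the start).

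Differences were tested in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) in 1 fit of 7 group means over all 20 arrays, so that every comparison shared an estimate of the spread per gene, with 13 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 among the genes tested in that comparison. Of the values entering the fit 1678 were missing. The number of arrays, 3 per group and 2 for 82hOP, limits the precision. Where a gene's probe was well above background on no array of 1 of the groups, its fold is given as "at least", from the mean of the bright group against, per dim array, the higher of the lowest signal well above background and the probe's own signal.

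A total of 42 gene lists (immune effectors, stress and detoxification families, metabolism, tissues and cell types of the worm) and a panel of 22 genes often used as reporters were fixed before the data were examined, as were the groups, tests, comparisons and most other settings. Lists were tested with limma's camera at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over lists within a comparison. The camera tests, list medians and within-slide list medians used the 15326 genes without a missing value; counts of list members used all tested members. At the preset correlation 170 of 480 list and comparison pairs passed, and 13 passed with an estimated correlation, in the same direction. These 13 were the p38 effectors and the CUB-like family after infection, in the matched comparison, with age and at 6 h and 12 h against the start, the metal response list after infection and at 12 h against the start, and the intestine list in the matched comparison. The lists described were chosen among the fixed ones after their results were seen.

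Genes named in the text were chosen from a larger set drawn by a fixed rule, except for 5 genes of propionate and folate metabolism in the closing section; some are also given in comparisons where the rule did not draw them. In the infection, 6 h recovery, matched, antibiotic and age comparisons the rule drew the 10 largest rises and 10 largest falls among genes past the threshold whose arrays did not overlap between groups; in the other comparisons the 5 and 5. The rule added up to 4 members with the smallest adjusted p of each list described, and the panel. The carry-over of the infection response into recovery was tested with limma's fry, a rotation test, with the infection genes as 1 set signed by their direction. Comparisons that shared a control group were set against 10000 simulated draws of unchanged groups that shared it; a control group of 3 cannot be split into parts of at least 2, so part of any excess may come from the shared arrays.

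Arrays with the same number deviated together from their group means in the infection comparison (r across genes of 0.587, 0.334 and 0.369 for numbers 1, 2 and 3), in the step from 6 h to 12 h of recovery (0.264, 0.349 and 0.779) and in the step from 12 h to 24 h (0.605, 0.704 and 0.808). The main fit did not pair these arrays. The number entered only as a block among the alternatives. This pairing comes from the data and partly coincides with the slide. Replicates correlated at r of 0.983 to 0.995 across probes, with no identical pairs. On simulated data for the infection comparison (15326 genes), the procedure recovered 79 of 100 genes changed by log2 1 and 92 of 100 changed by log2 2, with 9 false calls among 15126 unchanged genes. Genes and arrays were drawn independently there, without slide effects, so these rates do not cover deviations that arrays of the data share.

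Alternatives were normexp background correction (offset 50), quantile normalization, scaling by the median of bright probes, the authors' table, no filter or a stricter filter on dim probes, the mean of a gene's probes, the replicate number or the slide as a block, only the 2 groups of a comparison in the fit, another variance model, stricter thresholds, other controls and each array left out in turn. Normexp ended many single-gene calls, and their number stands in the closing section. Data were read with Python 3.11.15 and numpy 2.4.6, handled with the package data.table (1.17.8) and plotted with matplotlib 3.10.9.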

Results

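The data set held 20 arrays of whole worms in 7 groups, which follow an acute bacterial infection of the intestine and its clearance by antibiotics. Worms were sampled before infection (72hOP, n = 3), after 4 h on Pseudomonas aeruginosa PA14 (76hPA, n = 3), and after 6 h (82hR), 12 h (88hR) and 24 h (100hR) of recovery on antibiotics and Escherichia coli OP50, with n = 3 each. Uninfected worms of 82 h without antibiotics (82hOP, n = 2) and with them (82hOPC, n = 3) served as controls of age and drug. Levels are given as log2 signal relative to each array's 75th percentile, as mean ± SD, and differences as log2 values with their SE and the adjusted p of limma's fit. The median SD of a gene between replicates lay between 0.08 (82hOP) and 0.16 (76hPA), and 15858 genes were tested.

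Whether 4 h on the pathogen changes expression was asked with 76hPA against 72hOP. The move also changed the food, and no group was moved to harmless or killed bacteria of that species. Infection therefore stands below for both, which cannot be told apart. The largest rise was in F55G11.2, a gene without a common name whose probe lies on chromosome IV at 12967501 to 12967608 of ce6. Its level went from −3.09 ± 0.19 (SD, n = 3) to 3.01 ± 0.10 (SD, n = 3), a difference of 6.10 (SE 0.22, adjusted p = 1.09e-10). Genes for C-type lectins, secreted sugar-binding proteins of which many respond to pathogens, were also among the largest rises: clec-3 rose by 5.10, clec-74 by 4.62 and clec-174 by 4.74, and clec-2 was at least 19.9-fold higher. The glutathione S-transferase gst-38 rose by 4.87 (SE 0.24, adjusted p = 2.62e-09), the CUB-like gene dod-17 by 4.26 (SE 0.09, adjusted p = 3.87e-13), and the claudin-like gene clc-12 was at least 33.5-fold higher. The largest fall was in Y38H6C.21 (−5.13, SE 0.51, adjusted p = 4.13e-06), with 1 of 3 arrays of 76hPA well above background, and its call was lost with normexp (adjusted p = 0.214). The flavin monooxygenase fmo-2 (chromosome IV, 10684221 to 10684280) fell by 4.63 (SE 0.26, adjusted p = 9.31e-09), the alcohol dehydrogenase adh-1 fell by 3.80, the acyl-CoA synthetase acs-2 fell by 3.57 and the S-adenosylmethionine synthetase sams-1 fell by 3.21. The acyl-CoA dehydrogenase acdh-1 (chromosome I, 6498745 to 6498804) fell by 3.44 (SE 0.62, adjusted p = 0.00111).

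Some lists of immune effector genes rose as groups, while C-type lectins split (below). Of 14 measured members of the CUB-like domain family, secreted proteins often induced by bacteria, 11 rose, none fell and 3 did not pass (12 higher and 1 lower adjusted over the list alone). Among them were dod-22 (3.87), C32H11.3 (3.88) and F55G11.8 (2.99). The median was 2.32, 2.43 with slide as a block, and 2.67 and 1.85 within slides 1 and 4 (camera adjusted p = 5.12e-19, adjusted p = 0.00212 with an estimated correlation). Of 15 effectors of the p38 kinase pathway, a conserved arm of worm immunity that overlaps this family, 11 rose and 1 fell (13 and 1 adjusted over the list alone), with irg-6 at 1.59 (1.59 to 5.99 over its 3 probes) and mul-1 at 2.15 (2.15 and 3.91 for its 2 probes). Their median was 1.35, 1.30 with slide as a block and 1.26 and 1.5 within slides 1 and 4 (camera adjusted p = 1.70e-14, adjusted p = 0.00212 with an estimated correlation). In a list of early pathogen response genes around the transcription factor zip-2, 4 of 9 rose (4 adjusted over the list alone), irg-3 by 3.0 (SE 0.10, adjusted p = 4.65e-11) and irg-2 by 1.70 (SE 0.36, adjusted p = 0.00409). Their median was 0.51, 0.44 with slide as a block, 0.83 and 0.29 within slides 1 and 4 (camera adjusted p = 7.56e-04, adjusted p = 0.301 with an estimated correlation). The list had a mean loading of 11 thousandths on the main direction of deviations within groups, along which slides 1 and 5 lay lower. This mean does not hold for each gene and group. In 76hPA irg-1 was higher in sample 1, on slide 1, than in sample 3, on slide 4 (below).

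Metal response genes also rose, 4 of 8 with none lower (4 adjusted over the list alone), with cdr-1 at 2.81 and cdr-4 at 1.31. Their median was 0.75, 0.66 with slide as a block and 0.56 and 0.73 within slides 1 and 4 (camera adjusted p = 4.26e-05, adjusted p = 0.00633 with an estimated correlation). Among 234 F-box A and MATH/BTB genes, likely adaptors of protein degradation, 51 rose and 7 fell (60 and 7 adjusted over the list alone), such as fbxa-24 (1.13). Their median was 0.11, 0.08 with slide as a block and 0.08 and 0.10 within slides 1 and 4 (camera adjusted p = 1.30e-06, adjusted p = 0.561 with an estimated correlation). C-type lectins split: 34 of 159 rose and 15 fell (37 and 18 adjusted over the list alone). Their mean was 0.23 and their median 0.02, which turned to −0.01 with slide as a block and to −0.003 with quantile normalization, and lay at −0.06 and 0.05 within slides 1 and 4. The camera call (adjusted p = 0.0462) was lost with slide as a block (adjusted p = 0.0679), with the replicate number as a block (adjusted p = 0.0501), with quantile normalization (adjusted p = 0.102) and in the other test (adjusted p = 0.713 with an estimated correlation).

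Cuticle collagens, made by the epidermis, fell: 51 of 143 were lower and 1 higher (55 and 2 adjusted over the list alone), including col-101 (−2.46) and col-160 (−2.75). Their median was −0.20, −0.24 with slide as a block and −0.31 and −0.15 within slides 1 and 4 (camera adjusted p = 1.00e-06, adjusted p = 0.603 with an estimated correlation). Collagens also had a positive mean loading on the main direction of deviations within groups (7.24 thousandths). Markers of body wall and pharyngeal muscle moved with them, 12 of 15 lower and none higher (12 adjusted over the list alone), with the troponin tnt-2 at −0.78 and mup-2 at −0.75. Their median was −0.63, −0.62 with slide as a block and −0.53 and −0.47 within slides 1 and 4 (camera adjusted p = 6.94e-07, adjusted p = 0.301 with an estimated correlation). UDP-glucuronosyltransferases, which conjugate foreign compounds, had 20 of 62 lower and 7 higher (21 and 11 adjusted over the list alone), such as ugt-53 (−1.97) and ugt-63 (−1.59). Their median was −0.16, also with slide as a block, and −0.27 and −0.17 within slides 1 and 4 (camera adjusted p = 0.0401, adjusted p = 0.713 with an estimated correlation).

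Of 17 desaturases and elongases 5 fell and 1 rose (6 and 1 adjusted over the list alone): elo-5 (−1.33), elo-6 (−1.74) and fat-5 (−1.10) fell and the desaturase fat-7 rose by 1.19. The list median was −0.18, −0.14 with slide as a block and −0.24 and −0.13 within slides 1 and 4. The camera call (adjusted p = 0.0128) was lost with slide as a block (adjusted p = 0.0511, and adjusted p = 0.416 with an estimated correlation). Genes of fatty acid breakdown went both ways, 10 of 41 lower and 5 higher (11 and 7 adjusted over the list alone), with hacd-1 at −2.1, cpt-4 at 2.31 and ech-9 at 1.47, and the list did not pass (camera adjusted p = 0.401).

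In total 2032 of 15850 genes passed after infection, 969 higher and 1063 lower, and 603 of them changed at least 2-fold. With slide as a block 2565 passed. Within slide 1 all of the 2025 genes with values kept their direction (median rise 0.67, median fall −0.86), and within slide 4 this held for 2022 of 2024 (0.63 and −0.55). With normexp background correction 539 genes passed, and the calls of clec-2 (adjusted p = 0.0636) and fat-7 (adjusted p = 0.116) were lost.

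**Figure D1:**
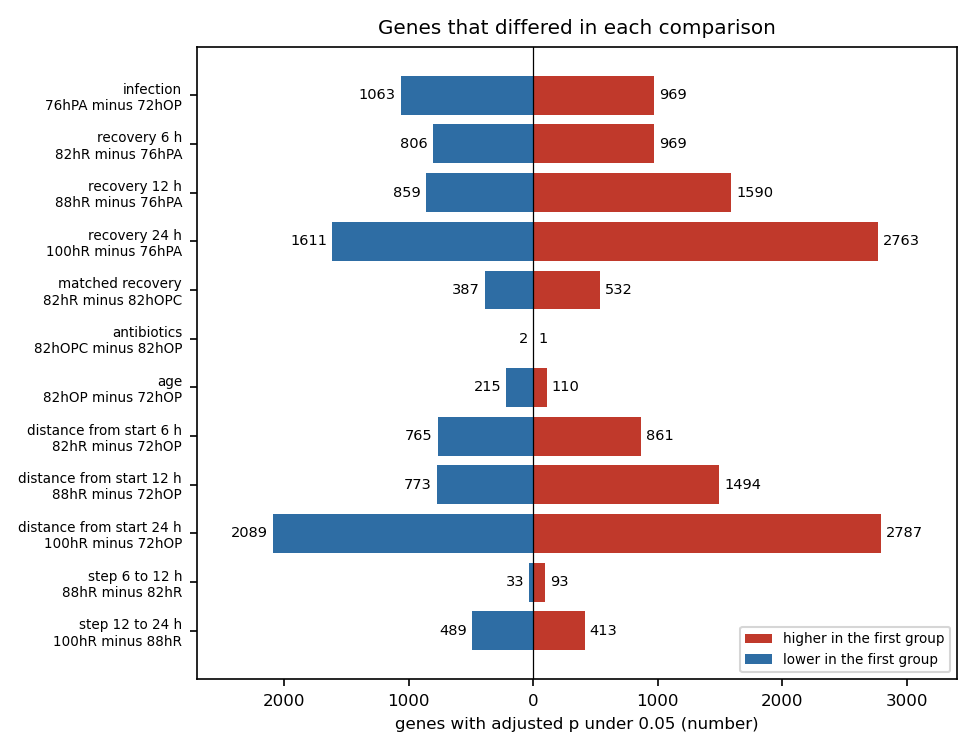
Number of genes past the adjusted p threshold of 0.05 in each of the 12 comparisons (bars start at 0), with genes higher and genes lower in the group named first. The infection comparison had 969 genes higher and 1063 lower, the antibiotic comparison 1 higher and 2 lower.

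Of the 22 panel genes 21 were measured; gst-4 was not tested. The starvation-responsive acs-2 went from 1.16 ± 0.26 (SD, n = 3) at the start to −2.41 ± 0.23 (SD, n = 3) after infection and to 1.85, 2.23 and 3.08 after 6 h, 12 h and 24 h of recovery, with 1.79 in 82hOP. The superoxide dismutase sod-3 fell by 1.08 after infection (adjusted p = 1.16e-07). The p38 targets C17H12.8 (1.29, adjusted p = 1.24e-04) and irg-4 (0.92, adjusted p = 0.00495) rose and the adult collagen col-19 fell by 0.74 (adjusted p = 3.58e-04). Another p38 target, sysm-1, did not pass, with 5.53 in 72hOP and 5.21 in 76hPA. Markers of protein folding stress in mitochondria and the endoplasmic reticulum did not pass, with hsp-6 at 0.03 (adjusted p = 0.911) and hsp-4 at an adjusted p of 0.995. Neither did the kinase gene pmk-1 (−0.10, adjusted p = 0.591), the lysozyme lys-7 (−0.23, adjusted p = 0.490) or the yolk protein vit-2 (0.04, adjusted p = 0.981). The early response gene irg-1 stood 3.2 higher (SE 0.97, adjusted p = 0.0397) with levels of 1.31, 0.99 and −1.89 in samples 1, 2 and 3 of 76hPA. Sample 3 was also the lowest at 6 h (−1.91), 12 h (−1.81) and 24 h (−0.98) of recovery. This call was lost without 72hOP 1 (adjusted p = 0.0904), 72hOP 2 (0.109), 72hOP 3 (0.0830), 76hPA 1 (0.173) or 76hPA 2 (0.143), and with normexp (0.144).

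Recovery was followed first against the infected state. After 6 h (82hR against 76hPA) several genes that had fallen after infection were among the largest rises: fmo-2 rose by 6.22 (SE 0.26, adjusted p = 1.08e-09), from −3.85 ± 0.36 to 2.37 ± 0.46 (SD, n = 3 each), adh-1 by 4.49, acs-2 by 4.26 and C45E5.1 by 3.70. The ammonium transporter gene amt-1 rose by 3.27 and the bestrophin gene best-1 by 3.28. The lectin genes clec-74 and clec-143 fell by 2.62 and 2.90 and gst-38 fell by 2.36. F55G11.3 fell by 3.23 (SE 0.35, adjusted p = 1.28e-05), and the cytochrome P450 gene cyp-35A1 fell by 2.75, with 1 of 3 arrays of 82hR well above background. With normexp the calls of clec-143 (adjusted p = 0.186) and cyp-35A1 (adjusted p = 0.885) were lost.

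Cytochromes P450, oxidases of foreign and endogenous compounds, fell at 6 h, 28 of 67 lower and 2 higher (31 and 5 adjusted over the list alone), with cyp-37B1 at −1.30, cyp-34A9 at −1.83 and cyp-13A5 at −1.69. Their median was −0.37, −0.39 with slide as a block and −0.25 within slide 3 (camera adjusted p = 7.15e-11, adjusted p = 0.165 with an estimated correlation). The CUB-like family had 7 of 14 lower and none higher (10 adjusted over the list alone), dod-17 at −1.13 and C32H11.3 at −1.67. Its median was −0.57, −0.50 with slide as a block and −0.46 within slide 3 (camera adjusted p = 1.44e-08, adjusted p = 0.0958 with an estimated correlation). Among C-type lectins 28 of 159 fell and 10 rose (34 and 12 adjusted over the list alone), including clec-66 (−0.98). The median was −0.19, −0.12 with slide as a block and −0.06 within slide 3 (camera adjusted p = 0.00107, adjusted p = 0.332 with an estimated correlation). Elongases rose, elo-5 by 2.34, elo-2 by 2.05 and elo-6 by 1.97, while fat-7 fell by 1.56; 6 of 17 genes of the desaturase and elongase list rose and 1 fell (6 and 1 adjusted over the list alone). The median was 0.27, 0.23 with slide as a block and 0.09 within slide 3 (camera adjusted p = 0.00197, adjusted p = 0.167 with an estimated correlation). UDP-glucuronosyltransferases had 17 of 62 higher and 9 lower (22 and 9 adjusted over the list alone), with ugt-63 at 1.45. Their median was 0.18, 0.23 with slide as a block and 0.31 within slide 3 (camera adjusted p = 0.0328, adjusted p = 0.664 with an estimated correlation). Collagens had 26 of 143 higher and 5 lower (27 and 6 adjusted over the list alone), col-98 at 1.96 and col-101 at 1.78, but the list did not pass (camera adjusted p = 0.327).

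At 6 h 1775 genes passed, 969 higher and 806 lower (2016 with slide as a block), and 1770 of 1772 kept their direction within slide 3, the only slide with both groups (median rise 0.70, median fall −0.58). The numbers grew with time, as did the age of the worms. At 12 h 2449 genes passed, 1590 higher and 859 lower (2543 with slide as a block, and 2425 of 2435 in the same direction within slide 4). At 24 h 4374 passed, 2763 higher and 1611 lower (4395 with slide as a block, and 4336 of 4353 within slide 4). With normexp 376, 532 and 1613 genes passed at the 3 times.

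The rises of fmo-2 (5.78 at 12 h and 4.86 at 24 h), adh-1 (4.6 and 4.79) and acs-2 (4.63 and 5.49) stood at the later times too, and C27H5.6 was at least 16.8-fold and at least 36.8-fold higher than in 76hPA. The infection-induced genes clec-74 (−3.57 and −4.49) and gst-38 (−3.16 and −3.94) were lower, and F55G11.2 was lower at 6 h (−1.80), 12 h (−2.65) and 24 h (−4.11, SE 0.22, adjusted p = 6.95e-09). The CUB-like family had 9 of 14 lower at 12 h (9 adjusted over the list alone; median −0.69, −0.81 with slide as a block, −0.70 within slide 4; camera adjusted p = 3.23e-09, adjusted p = 0.0847 with an estimated correlation). At 24 h 10 were lower (10 adjusted over the list alone), with dod-17 at −3.03 and C32H11.3 at −3.11. The median was then −1.22, −1.13 with slide as a block and −1.19 within slide 4 (camera adjusted p = 2.12e-09, adjusted p = 0.0789 with an estimated correlation). Collagens rose at 12 h, 39 of 143 higher and 2 lower (41 and 4 adjusted over the list alone), with col-160 at 3.35 and col-98 at 2.54 but col-135 at −2.34. Their median was 0.13, 0.20 with slide as a block and 0.18 within slide 4 (camera adjusted p = 0.0115, adjusted p = 0.613 with an estimated correlation).

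At 24 h further groups differed from the infected state. Of 25 pals genes, a family linked to the response to intracellular pathogens, 12 rose and none fell (14 adjusted over the list alone), pals-14 by 1.76 and pals-6 by 1.45. Their median was 0.69, 0.64 with slide as a block and 0.52 within slide 4 (camera adjusted p = 1.34e-04, adjusted p = 0.622 with an estimated correlation). UDP-glucuronosyltransferases had 27 of 62 higher and 10 lower (30 and 12 adjusted over the list alone), ugt-53 at 2.01 and ugt-66 at 1.88. Their median was 0.31, 0.36 with slide as a block and 0.18 within slide 4 (camera adjusted p = 0.0320, adjusted p = 0.742 with an estimated correlation). This call was also lost with quantile normalization (adjusted p = 0.0764). Genes first transcribed in the early embryo fell, 23 of 40 lower and 4 higher (23 and 7 adjusted over the list alone), with the T-box genes tbx-37 at −2.40 and tbx-38 at −2.17, the latter's call being lost with normexp (adjusted p = 0.340). Their median was −0.63, −0.71 with slide as a block and −0.72 within slide 4 (camera adjusted p = 1.88e-06, adjusted p = 0.545 with an estimated correlation). The name of this list does not stand for embryo content here or below. The worms carried the temperature-sensitive fer-1 allele at 25 °C, and embryos were not assessed.

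**Figure D2:**
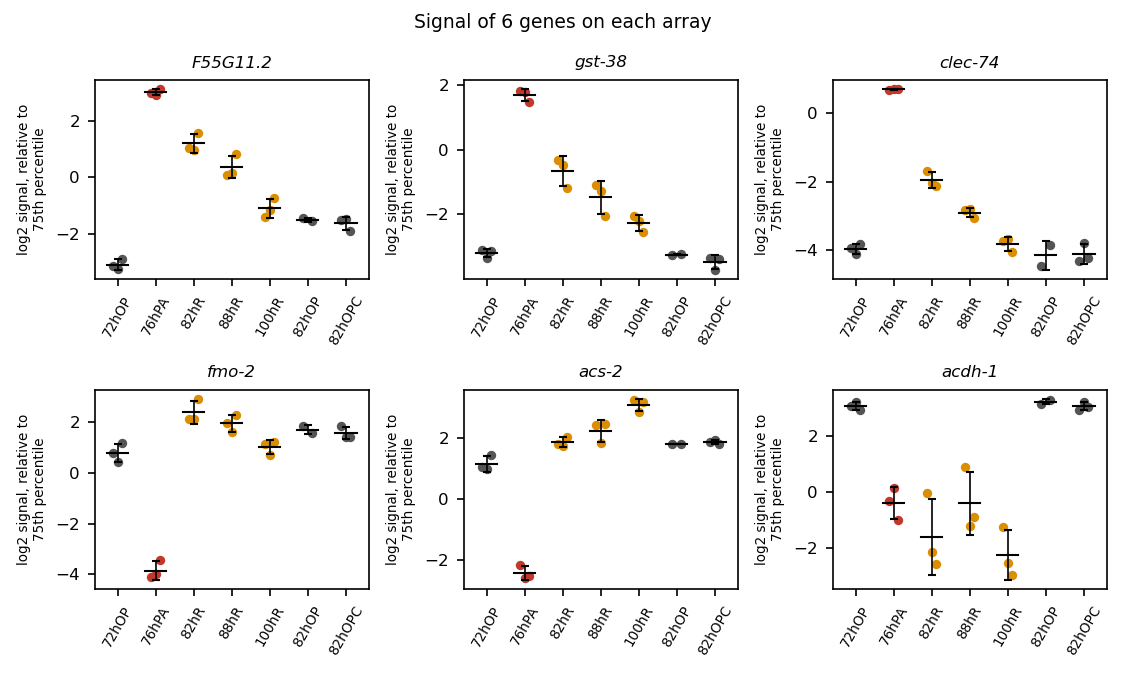
Levels of F55G11.2, gst-38, clec-74, fmo-2, acs-2 and acdh-1 on every array (points), with the group mean (line) and SD (bar), as log2 signal relative to the array's 75th percentile, for the 7 groups. F55G11.2 went from −3.09 in 72hOP to 3.01 in 76hPA and −1.1 in 100hR, and acdh-1 from 3.06 in 72hOP to −0.38 in 76hPA and −2.24 in 100hR.

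Across 15326 genes, changes during recovery ran against those of infection, but both share the 76hPA arrays, which alone gives a negative relation. The covariance was −0.108, −0.122 and −0.115 at 6 h, 12 h and 24 h, against −0.0385, −0.0393 and −0.0388 simulated for unchanged groups, with SDs of 0.0412, 0.0419 and 0.0416 between draws. The differences were −0.0696, −0.0823 and −0.0761. The correlations across genes, which are not independent replicates, were −0.548, −0.548 and −0.420, against simulated values of −0.464, −0.470 and −0.467. At 24 h the correlation was thus weaker than for unchanged groups, while the covariance was larger in size. These values leave open whether there was a reversal beyond the shared arrays.

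Between consecutive recovery times, which also differ in age, few genes differed at first. From 6 h to 12 h 126 genes passed, 93 higher and 33 lower, and 327 with slide as a block and 224 with the replicate number as a block. Of those with values 126 of 126 and 125 of 125 kept their direction within slides 2 and 5 (medians of the rises 0.70 and 0.71, of the falls −0.63 and −0.59). F56D6.9 rose by 1.76 (SE 0.21, adjusted p = 0.00104), and the collagen gene col-135 fell by 1.23 (SE 0.11, adjusted p = 1.26e-04). Of 67 cytochromes P450 4 rose and none fell (18 adjusted over the list alone), cyp-37B1 by 0.72 and cyp-35B1 by 0.99. Their median was 0.26, 0.27 with slide as a block and 0.27 and 0.30 within slides 2 and 5 (camera adjusted p = 1.80e-11, adjusted p = 0.210 with an estimated correlation). The count fell to 46 without 82hR 1, 73 without 82hR 3, 70, 44 and 37 without 88hR 1, 2 and 3, and 3 with normexp, where cyp-37B1 (adjusted p = 0.197) and cyp-35B1 no longer passed.

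From 12 h to 24 h 902 genes passed, 413 higher and 489 lower, with 1558 with slide as a block and 1365 with the replicate number as a block. The collagen gene col-183 rose by 2.54 (SE 0.16, adjusted p = 1.60e-06) and ZK355.3 by 2.31, and dod-17 fell by 1.26. C41G6.13, whose probe also lists another gene, rose by 3.61 (SE 0.59, adjusted p = 0.00292). Of 43 antimicrobial peptide genes of the epidermis 8 rose and none fell (10 and 1 adjusted over the list alone), fipr-26 by 1.44 and fipr-23 by 0.91. Their median was 0.24, also with slide as a block, and 0.22, 0.26 and 0.20 within slides 2, 4 and 5 (camera adjusted p = 0.00123, adjusted p = 0.720 with an estimated correlation). These genes also had a positive mean loading on the main direction of deviations within groups (5.96 thousandths). Of the 40 early embryonic genes 14 fell and 1 rose (17 and 1 adjusted over the list alone), tbx-37 at −0.95. Their median was −0.35, also with slide as a block, and −0.44, −0.30 and −0.32 within slides 2, 4 and 5 (camera adjusted p = 3.24e-09, adjusted p = 0.350 with an estimated correlation). Of 14 CUB-like genes 7 fell (9 adjusted over the list alone). Their median was −0.49, also with slide as a block, and −0.52, −0.45 and −0.39 within the 3 slides (camera adjusted p = 1.12e-07, adjusted p = 0.147 with an estimated correlation). Within slides 2, 4 and 5 899 of 899, 897 of 897 and 895 of 896 genes kept their direction (median rises 0.59, 0.57 and 0.57, median falls −0.49, −0.44 and −0.44). The count fell to 532, 601 and 454 without 88hR 1, 2 and 3, to 450, 495 and 582 without 100hR 1, 2 and 3, and to 115 with normexp, under which tbx-37 (adjusted p = 0.845), dod-17 (0.0835) and fipr-26 (0.0745) no longer passed. The normexp median over all genes was 0.253 in this step, which works against falls.

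What an earlier infection leaves behind was asked with 82hR against 82hOPC, worms of the same labelled age and antibiotics that had never met PA14. The earlier food differed as well, so effects of infection and of food cannot be told apart here either. The lectin gene clec-174 stood higher by 3.77 (SE 0.36, adjusted p = 2.04e-05), F55G11.2 by 2.83 (SE 0.22, adjusted p = 2.02e-06), gst-38 by 2.80 and irg-3 by 2.21 (SE 0.10, adjusted p = 3.90e-09). The gene cld-1, whose probe also lists another gene, stood 4.05 higher (SE 0.55, adjusted p = 3.54e-04). The acyl-CoA dehydrogenase gene acdh-1 fell from 3.05 ± 0.15 in 82hOPC to −1.59 ± 1.35 in 82hR (SD, n = 3 each). The difference was −4.64 (SE 0.62, adjusted p = 3.29e-04; −5.04 with slide as a block), and T13F3.6 was at −2.53. The gene vmo-1, named for an egg yolk membrane protein, was at least 12.3-fold lower, a call that was lost with normexp (adjusted p = 0.564), as was that of C49F5.9 (−2.86, and −3.13 to −1.51 over its 8 probes; adjusted p = 0.263).

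Of 15 p38 effectors 9 were higher and 1 lower (13 and 1 adjusted over the list alone), among them dod-22 (1.57), mul-1 (1.20, and 1.93 for its other probe) and clec-67 (1.33). Their median was 0.63, 0.67 with slide as a block and 0.60 and 1.04 within slides 3 and 5 (camera adjusted p = 2.03e-11, adjusted p = 0.0106 with an estimated correlation). The CUB-like family had 10 of 14 higher and none lower (11 adjusted over the list alone). Its median was 0.66, 0.64 with slide as a block and 0.63 and 1.06 within slides 3 and 5 (camera adjusted p = 3.79e-12, adjusted p = 0.0149 with an estimated correlation). Of the 9 early pathogen response genes only irg-3 passed over all genes (4 higher adjusted over the list alone). The median was 0.75, 0.81 with slide as a block, but 0.91 and 0.04 within slides 3 and 5 (camera adjusted p = 3.87e-05, adjusted p = 0.141 with an estimated correlation). Intestine markers moved with the immune genes, 6 of 16 higher and 1 lower (8 and 2 adjusted over the list alone), with the intestinal GATA factor elt-2 at 0.40, the actin act-5 at 0.74 and the peptide transporter pept-1 at 0.90. Their median was 0.24, 0.26 with slide as a block and 0.34 and 0.26 within slides 3 and 5 (camera adjusted p = 4.26e-05, adjusted p = 0.0369 with an estimated correlation). With normexp the calls of elt-2 (adjusted p = 0.210), act-5 (0.0906) and pept-1 (0.0590) were lost, as were those of lys-5 (0.107) and the early embryonic gene sdz-4 (0.282).

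Collagens were lower, 24 of 143 against 1 higher (34 and 2 adjusted over the list alone), including col-157 at −0.96. Their median was −0.25, −0.35 with slide as a block and −0.38 and −0.25 within slides 3 and 5 (camera adjusted p = 1.40e-07, adjusted p = 0.459 with an estimated correlation). Of 67 cytochromes P450 9 were lower and none higher (10 adjusted over the list alone), cyp-34A9 at −1.0 and cyp-34A8 at −0.71. Their median was −0.14, also with slide as a block, and −0.26 and −0.13 within slides 3 and 5 (camera adjusted p = 4.26e-05, adjusted p = 0.459 with an estimated correlation). Lysozymes had 3 of 15 lower and none higher (8 and 3 adjusted over the list alone), lys-5 at −0.69. Their median was −0.59, also with slide as a block, and −0.51 and −0.46 within slides 3 and 5 (camera adjusted p = 0.0282, adjusted p = 0.434 with an estimated correlation). The list call was also lost with quantile normalization (adjusted p = 0.0942). Among single genes, the call of lys-10 was lost with normexp and without 82hR 1, 82hR 2 or any array of 82hOPC. That of lys-6 was lost with normexp and without 82hR 1 or 82hOPC 2. Early embryonic genes were higher, 10 of 40 with none lower (19 and 1 adjusted over the list alone), sdz-4 at 0.57. Their median was 0.28, 0.24 with slide as a block and 0.20 and 0.17 within slides 3 and 5 (camera adjusted p = 3.16e-06, adjusted p = 0.434 with an estimated correlation). The single calls hung on particular arrays. Of 30 sdz genes, which belong to this list, 8 were higher. This count was 1 without 82hOPC 1, 2 without 82hOPC 2, 82hR 1 or 82hR 3, and 0 with normexp. It was 8 without 82hR 2 and 12 without 82hOPC 3.

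In this comparison 919 genes passed, 532 higher and 387 lower (1042 with slide as a block). Within slides 3 and 5 all of the 917 and 915 genes with values kept their direction, with median rises of 0.61 and 0.44 and median falls of −0.60 and −0.52. Scaling by the median of bright probes moved the share of higher genes from 57.9% to 47.2%. The count fell to 467 without 82hR 1, 481 without 82hOPC 1, 509 without 82hOPC 2, and 111 with normexp.

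The infection response was partly present in this comparison, which shares no array with the infection comparison. Of the 2032 infection genes 1620 (79.7%) had the same sign in 82hR against 82hOPC, with a slope through the origin of 0.394, 0.388 with slide as a block in both, and r of 0.710 across genes, which are not independent replicates. Taken as a set signed by direction, they moved the same way in limma's fry, a rotation test that allows for correlated genes (fry p = 5.97e-06, and 6.97e-05 with slide as a block). Genes past both thresholds numbered 267 higher in both, where independent lists would share 32.5, and 223 lower in both, where they would share 26. A further 16 rose after infection and were lower here (23.7 for independent lists), and 18 fell after infection and were higher here (35.7).

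**Figure D3:**
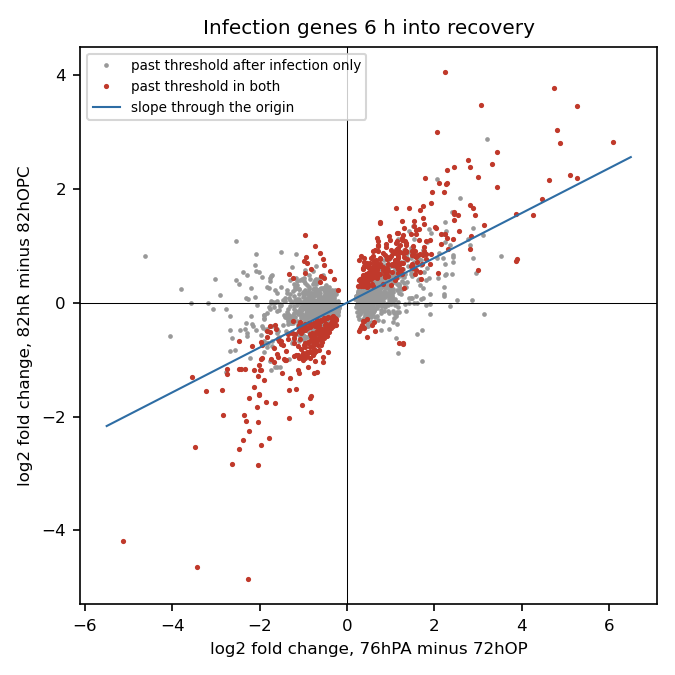
Log2 difference of each gene in 82hR against 82hOPC (vertical axis) plotted on its log2 difference in 76hPA against 72hOP (horizontal axis), with genes past the threshold in both comparisons and after infection only marked by colour. The slope through the origin over the 2032 infection genes was 0.394, and 1620 of them had the same sign in both.

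Against the starting worms, which differ also in age and antibiotics, the recovering worms stood further away with time: 1626 genes at 6 h (861 higher), 2267 at 12 h (1494 higher) and 4876 at 24 h (2787 higher), and 2087, 2652 and 5382 with slide as a block. F55G11.2 remained higher by 4.30 at 6 h, 3.45 at 12 h and 1.99 at 24 h, and Y60C6A.1 stood 4.33, 5.2 and 6.18 higher (SE 0.57; 1 of 3 arrays of 72hOP well above background). Lower throughout were acdh-1 (−4.65, −3.46 and −5.30) and C49F5.9 (−3.03, −3.28 and −4.31). The calls of C49F5.9 were lost with normexp (adjusted p = 0.130, 0.0958 and 0.0715). The p38 effectors had 8, 11 and 11 of 15 higher (13, 13 and 11 adjusted over the list alone, and 1 lower at 24 h), dod-22 at 3.35, 2.88 and 1.87. Their medians were 0.97, 0.90 and 0.65 and 0.98, 1.02 and 0.70 with slide as a block, and 1.13, 1.20 and 0.73 within slide 2 and, at 12 h and 24 h, 0.91 and 0.63 within slide 4 (camera adjusted p = 3.04e-15, 1.56e-12 and 5.71e-05; adjusted p = 0.00251, 0.00624 and 0.188 with an estimated correlation). Metal response genes were higher at 12 h, 4 of 8 with none lower (5 adjusted over the list alone), with cdr-1 at 0.99. Their median was 0.63, 0.54 with slide as a block and 0.44 and 0.65 within slides 2 and 4 (camera adjusted p = 9.95e-04, adjusted p = 0.0287 with an estimated correlation). Cytochromes P450 had 23 of 67 lower and 2 higher at 6 h (25 and 3 adjusted over the list alone), cyp-37B1 at −0.94. Their median was −0.25, −0.28 with slide as a block and −0.16 within slide 2 (camera adjusted p = 6.28e-08, adjusted p = 0.214 with an estimated correlation).

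The pals genes stood above the start late in recovery, 12 of 25 higher at 12 h and 19 at 24 h with none lower (17 and 21 adjusted over the list alone), pals-27 by 1.93 and pals-14 by 1.78 at 24 h. The medians were 0.77 and 1.24, 0.64 and 1.1 with slide as a block, 0.80 and 1.38 within slide 2 and 0.45 and 0.80 within slide 4 (camera adjusted p = 2.50e-07 and 1.55e-08; adjusted p = 0.304 and 0.308 with an estimated correlation). At 24 h 83 of 234 F-box A and MATH/BTB genes were higher and 26 lower (87 and 28 adjusted over the list alone), fbxa-3 by 1.06. The median was 0.22, 0.24 with slide as a block and 0.39 and 0.15 within slides 2 and 4 (camera adjusted p = 0.00702, adjusted p = 0.692 with an estimated correlation). With quantile normalization the list call was lost too (adjusted p = 0.0551, median 0.14). Mitochondrial ribosomal proteins had 20 of 70 lower and none higher (20 adjusted over the list alone), mrpl-54 at −0.51. Their median was −0.13, −0.10 with slide as a block and −0.11 and −0.07 within slides 2 and 4 (camera adjusted p = 1.03e-04, adjusted p = 0.659 with an estimated correlation). Between 99.8% and 100% of the genes past the threshold at the 3 times kept their direction within slides 2 and 4. The count at 6 h fell to 1037 without 82hR 1; normexp left 275, 266 and 1966, and scaling by the median of bright probes moved the share of higher genes at 24 h from 57.2% to 45.6%. The covariance with the infection response, which shares 72hOP, was 0.122, 0.108 and 0.115 at the 3 times against simulated 0.0393, 0.0385 and 0.0390. The SDs between draws were 0.0417, 0.0414 and 0.0415. The correlations were 0.595, 0.504 and 0.421 against simulated 0.475, 0.461 and 0.470, so at 24 h the correlation was the weaker.

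The antibiotics themselves were tested in uninfected worms (82hOPC against 82hOP). The transthyretin-like gene ttr-29 was higher by 1.19 (SE 0.16, adjusted p = 0.0131; within slides 1 and 3 by 1.1 and 1.33). The receptor gene srh-149 was at least 3.10-fold lower (adjusted p = 0.0416) and the potassium channel gene twk-32 at least 1.72-fold lower (adjusted p = 0.00149). The same 2 arrays of 82hOP also stood above 72hOP in both genes, srh-149 at least 2.93-fold (adjusted p = 0.00569) and twk-32 at least 1.63-fold (adjusted p = 4.59e-04). The call of srh-149 against 72hOP was lost when either array of 82hOP was left out, which leaves only 1 array in that group. With normexp the calls of both genes against 72hOP were lost. No other of 15824 genes passed with limma. An unadjusted p under 0.05 was reached by 287, a smaller share than the 0.05 that unchanged genes give on average. With slide as a block 2 passed, without srh-149 (adjusted p = 0.154). Without 82hOP 2 none passed, the adjusted p being 0.232 for ttr-29, 0.489 for srh-149 and 0.0528 for twk-32. Without 82hOPC 1, 2 or 3 only 1 passed, since ttr-29 (0.0670, 0.0711 and 0.0603) and srh-149 (0.153, 0.164 and 0.239) were lost. Without 82hOP 1 also 3 genes passed, but of those above only twk-32, since ttr-29 (0.114) and srh-149 (0.225) were lost. With normexp none passed. Of 29 neuropeptide genes of the flp family none passed singly or adjusted over the list alone, flp-3 at 0.32. The list stood higher with a median of 0.11, 0.12 with slide as a block and 0.14 and 0.18 within slides 1 and 3 (camera adjusted p = 6.19e-06, adjusted p = 0.991 with an estimated correlation). None of 76 cytosolic ribosomal protein genes passed either (0 adjusted over the list alone), rps-19 at −0.28 (−0.28 to −0.13 over its 6 probes). Their median of −0.17 (camera adjusted p = 4.53e-09, adjusted p = 0.991 with an estimated correlation) became −0.02 with slide as a block (adjusted p = 0.429) and 0.02 with quantile normalization, and lay at 0.02 and −0.05 within slides 1 and 3.

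Ageing by 10 h on OP50 (82hOP against 72hOP) changed 325 of 15817 genes, 110 higher and 215 lower (481 with slide as a block), and all 321 with values kept their direction within slide 1 (median rise 0.72, median fall −0.81). The CUB-like genes dod-17 (1.76, SE 0.10, adjusted p = 7.38e-07), dod-22 (1.63), C32H11.3 (1.68) and F55G11.8 (1.39) rose without infection. Of the 14 members 8 rose and 1 fell (9 and 1 adjusted over the list alone). Their median was 0.49, 0.63 with slide as a block and 0.77 within slide 1 (camera adjusted p = 1.08e-11, adjusted p = 0.0235 with an estimated correlation). Of 15 p38 effectors 5 rose and none fell (7 adjusted over the list alone), with catp-3 at 0.68. Their median was 0.40, 0.38 with slide as a block and 0.34 within slide 1 (camera adjusted p = 3.48e-08, adjusted p = 0.0235 with an estimated correlation). Early embryonic genes fell, 8 of 40 with none higher (21 and 5 adjusted over the list alone), tbx-37 at −1.29. Their median was −0.43, −0.42 with slide as a block and −0.53 within slide 1 (camera adjusted p = 3.47e-09, adjusted p = 0.302 with an estimated correlation). The call of tbx-37 was lost with normexp. Further falls were in nta-1 (−1.85, SE 0.25, adjusted p = 0.00189) and cyp-33D3 (−1.76), and F35E8.10, whose probe also lists another gene, rose by 2.01. The count fell to 186 without 72hOP 1, 165 without 72hOP 3, 41 without 82hOP 1 and 66 without 82hOP 2, and to 17 with normexp, under which nta-1 (adjusted p = 0.147), catp-3 (0.405) and cyp-33D3 no longer passed.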

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

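The tests of 24 h against 6 h of recovery, of the infection effect against the matched effect, of dim probes, of worm cultures and of age with antibiotics were chosen only after the results they concern were seen. A difference between times or effects brought up 4 results. The steps from 6 h to 12 h and from 12 h to 24 h of recovery changed 126 and 902 genes, and 24 h against 6 h changed 2754 genes, 1700 higher and 1054 lower (3414 with slide as a block). The infection effect differed from the matched effect at 6 h of recovery in 651 genes, 268 above and 383 below (733 with slide as a block). Among them were fmo-2 (−5.45, SE 0.36, adjusted p = 6.90e-07), adh-1 (−4.03), acs-2 (−3.56), F55G11.2 (3.27, SE 0.31, adjusted p = 1.46e-05) and C32H11.3 (3.15). A signal in probes that no gene table matched brought up the last one: 68 of 3383 such probes passed after infection, 28 higher and 40 lower, against 0 of 3382 with limma in the antibiotic comparison. Among matched genes 2032 of 15850 passed after infection, a larger share, and 3 of 15824 in the antibiotic comparison.

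Of 5 genes of the propionate shunt, which breaks down propionate when vitamin B12 is scarce, 4 were lower after infection and in the matched comparison. After infection acdh-1 fell by 3.44, hphd-1 by 2.36, ech-6 by 0.60 and hach-1 by 0.40, while alh-8 did not pass (adjusted p = 0.154, and 0.453 in the matched comparison), and the mean over the 5, carried by acdh-1 and hphd-1, was −1.47. In 82hR against 82hOPC the mean was −1.58, and −0.819 without acdh-1. The values argued against age and antibiotics as the cause, with a mean of −0.0298 in 82hOPC against 72hOP, and against the slide, with −1.66 in the matched comparison with slide as a block. A biological explanation, that worms took up vitamin B12 from PA14, predicted a lower mthf-1 before that gene was looked at; mthf-1 was at −0.478 (adjusted p = 0.0200), which is in line with it but does not exclude other causes, and B12 itself was not measured.

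Arrays of a group deviated along a main direction that followed the slide, with all arrays of slides 1 and 5 on one side and all others on the other. It held 44.9% of the variance of the deviations, with mean loadings (in thousandths, positive where slides 1 and 5 lay lower) of 11 for the early pathogen response list, 7.24 for collagens and 5.96 for epidermal antimicrobial peptides, against 0.286 for the CUB-like family. The values argued against probe GC content as the cause (r = 0.115 across 15326 genes). They also argued against dim probes as the only cause. Among 13371 bright genes alone all 20 arrays stayed on their slide's side, and the main direction held 42.2% of the variance. As the loading correlated with mean signal at r = −0.285 across genes, dim probes may still add to this direction. Whether worm cultures that share a number or the slide caused it stayed open: same-number arrays on different slides correlated at 0.0694 (34 pairs) and arrays of a slide with different numbers at 0.167 (7 pairs). No biological explanation beyond shared cultures was tested.

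The infection and age comparisons shared genes. Of the 325 age genes 37.5% were infection genes, 33 higher in both against 6.73 for independent lists and 34 lower in both against 14.4. The 2 comparisons share 72hOP, and over all genes there was no excess over unchanged groups that share it: the covariance was 0.0351 against 0.0390 simulated (SD 0.0458) and the correlation 0.218 against 0.416. The 4 h of age between 76hPA and 72hOP were an unlikely cause of the infection response, since 73.9% of the infection genes passed in the same direction against the older 82hOP. With slide as a block 94.8% of the infection genes passed in the same direction. Those genes were selected on the same arrays, so this share is a description and cannot by itself exclude the slide. Opposite directions were also shared, 34 higher after infection and lower with age against 13.2, and 21 the other way against 7.34.

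Other groupings of the same arrays could not tell real from chance differences, because 6 arrays allow only 10 splits. The true grouping was the only 1 of 10 with as many genes past the threshold in each of the 10 comparisons of 3 against 3. The highest other count was 3 after infection, 1 at each recovery time against 76hPA, 0 in the matched comparison and against the start, 1 from 6 h to 12 h and 5 from 12 h to 24 h.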

How the results depend on the processing

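The tests without slides 1 and 5 and with outlier spots kept were chosen only after the results were seen. Quantile normalization, scaling by bright probes, the mean of a gene's probes, other variance models, outlier spots kept and other controls left every count within 1.5 times, apart from those below. The carry-over slope kept its sign and its p under 0.05 (0.363 to 0.441) in the settings run for it: infection genes from quantile normalization or of at least 2-fold, slide as a block, and each 82hR or 82hOPC array left out. The differences from simulated covariance kept their sign with quantile normalization and with slide as a block (−0.0982 to −0.0696). Neither was run with normexp or the replicate block. Gene list calls fell from 170 to 13 with an estimated correlation, and were 140 with quantile normalization, 168 with slide as a block and 164 with the replicate block. Of 375 gene calls drawn by the rule for naming genes, of which the text gives a part, 174 were lost with normexp, 14 with quantile normalization, 10 with slide as a block and 3 with the replicate block, and 228 losses came from leaving out 1 array. Of the 2032 infection genes 50 were dim in 1 group, where folds are lower bounds. The median residual SD was 0.274 with normexp against 0.159. The cause was not tested for any change below unless stated.

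In the order infection, recovery at 6 h, 12 h and 24 h, matched, antibiotics, age, start at 6 h, 12 h and 24 h, and the 2 steps, normexp gave 539, 376, 532, 1613, 111, 0, 17, 275, 266, 1966, 3 and 115 genes. An adjusted p under 0.01 gave 1334, 1124, 1588, 2912, 370, 1, 97, 850, 1110, 3105, 43 and 327, by its own construction. A change of at least 2-fold gave 603, 423, 577, 1045, 176, 65, 395, 434, 1016, 30 and 83, without the antibiotic comparison, where all 3 stayed. Without slides 1 and 5, thus with fewer arrays, 987, 678, 1032, 2308, 151, 0, 4, 753, 889, 2598, 0 and 28 passed. With only the groups compared, thus with fewer arrays, the infection comparison gave 1113, recovery 677 (6 h) and 1267 (12 h), the matched comparison 160, age 0, start 612 (6 h) and 1076 (12 h), and the steps 1 and 549. Some comparisons gave 0 with limma in a smaller fit. At an unadjusted p under 0.05 in the full fit, age had 1781 genes and the first step 1495. Antibiotics had 287, a smaller share than the 0.05 that unchanged genes give on average.

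Antibiotics gave 5 genes and the step from 6 h to 12 h 83 without a filter on dim probes, antibiotics 1 with probes bright on all arrays, and the authors' values gave 1 and 74 for the same 2 comparisons. With slide as a fixed block the steps gave 327 and 1558, and with slide as a random block the matched comparison gave 1424, antibiotics 5, age 583 and the steps 377 and 1736. With the replicate block antibiotics gave 5, age 509 and the steps 224 and 1365; the others were 2411 (infection), 2167, 3078 and 5168 (recovery), 1317 (matched), and 2128, 3048 and 5777 (start). Outside the infection comparison and the steps, the samples that correlated best with their own number were 3, 1 and 0 of 6 in recovery and 4 of 6 in the matched comparison. They were 3 of 4 for antibiotics, 3 of 4 for age and 0, 2 and 2 of 6 against the start. Pairs that shared a slide as well as a number were number 2 at 6 h of recovery, numbers 2 and 3 in the matched comparison, numbers 1 and 2 for antibiotics and number 1 for age. The correlations of same-number pairs were −0.183, 0.360 and 0.0522 at 6 h, −0.182, 0.193 and −0.0748 at 12 h and −0.225, 0.231 and −0.0707 at 24 h of recovery, and 0.0617, 0.598 and 0.484 in the matched comparison. They were 0.258 and 0.594 for antibiotics, 0.547 and 0.348 for age, and −0.280, 0.204 and −0.201, −0.143, 0.438 and −0.265, and −0.298, 0.439 and −0.216 against the start.

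Leaving out 1 array gave a range of 1581 to 2056 genes after infection, 1276 to 1915, 1835 to 2833 and 3478 to 4682 in recovery, 467 to 995 in the matched comparison, 0 to 3 for antibiotics and 41 to 353 with age. Against the start it gave 1037 to 1374, 1550 to 2016 and 3876 to 4564, and in the steps 37 to 105 and 450 to 601; where 82hOP kept 1 array, that array was assumed to vary like the other groups. Reversed under normexp were set-15 at 24 h against the start (0.34) and, in the step from 12 h to 24 h, C35D6.11 (0.67), F11G11.14 (0.89), nhr-155 (0.50), sdz-7 (0.0055), sdz-18 (0.28) and tbx-38 (0.31). With normexp the median over all genes was 0.267 at 24 h of recovery, 0.283 at 24 h against the start and 0.253 in that step. In the main fit it was 0.0258, 0.00908 and −0.00276. Elsewhere the normexp medians lay between −0.0489 and 0.0255. The shift favours rises in 100hR and works against falls, so it enters these reversals. The list of cytosolic ribosomal proteins in the antibiotic comparison reversed under quantile normalization (adjusted p = 0.884, median 0.02).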

Other observations

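The tests of gene families by name (one-sided Fisher tests that treat genes as independent, adjusted over 161 or 162 families) were chosen only after the data were seen, as were their alternatives. Transthyretin-like genes, secreted proteins of mostly unknown function, were often among the falls after infection, 17 of 52 lower and 4 higher (adjusted p = 1.25e-06 for the falls, 20 lower with slide as a block, 6 lower with normexp, adjusted p = 0.0379). By 24 h of recovery 32 of them stood above the infected state and 6 below it (adjusted p = 2.36e-10 for the rises, 34 above with slide as a block, 16 above with normexp, adjusted p = 6.86e-06). The normexp median over all genes was 0.267 in that comparison, which favours rises. In the matched comparison 12 transthyretin-like genes were lower (adjusted p = 2.61e-07, and 15 with slide as a block), a result lost with normexp (3, adjusted p = 0.0539). Without 82hR 1 or 82hOPC 2 the count was 5 (adjusted p = 0.0309) or 6 (adjusted p = 0.0035). Of 20 skr genes, ubiquitin ligase subunits, 11 were lower and 1 higher at 24 h than in the infected state (adjusted p = 3.28e-05 for the falls, 10 lower with slide as a block, 8 lower with normexp, adjusted p = 3.16e-05).

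Of 99 F-box B genes, likely adaptors of protein degradation, 35 were lower and 14 higher at 24 h than in the infected state (adjusted p = 1.07e-09 for the falls, and 38 lower with slide as a block). Of 30 sdz genes, which depend on the embryonic factor SKN-1, 20 were lower and 2 higher (adjusted p = 2.20e-11 for the falls, and 21 lower with slide as a block). With normexp 7 and 1 passed, and neither family did (adjusted p = 0.901 for the former). The normexp median over all genes was 0.267 in that comparison, which works against falls. In the matched comparison 36 fbxb genes were higher (adjusted p = 7.55e-26; 34 with slide as a block), a result lost with normexp (adjusted p = 1) and without 82hOPC 1 (6, adjusted p = 0.253). Without 82hR 1, 82hR 3 or 82hOPC 2 the count was 14, 16 or 18. At 6 h of recovery 6 of 11 prx genes of peroxisome biogenesis were lower (adjusted p = 3.39e-04; 4 with slide as a block, adjusted p = 0.0472), a result lost with normexp (adjusted p = 0.202).

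Several lists did not pass after infection. Of 8 components of the p38 pathway itself 1 was higher (camera adjusted p = 0.861), of 13 heat shock genes 2 were higher (adjusted p = 0.184), of 19 genes of the endoplasmic reticulum stress response 1 was lower (adjusted p = 0.706), and of 9 of the mitochondrial one none passed with limma (adjusted p = 0.484). Of 56 sperm genes 3 were lower (adjusted p = 0.0530).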
